A study of Mus musculus with 18 samples.

How the data were processed

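The samples were mouse dermal fibroblasts of a male 129/S6 line, immortalized with SV40, labelled as lacking macroH2A1 and macroH2A2 and as carrying a doxycycline-inducible macroH2A2-GFP transgene. Doxycycline was given at 0.5 ug/ml for 6h, 24h or 5d. Native ChIP-seq with GFP-Trap after MNase digestion had 1 library each at 0h, 6h, 24h and 5d, at 24h with 0.5 uM flavopiridol for the last 18 hours, and at 6h and 24h after 10 days of 5 uM GSK126. A further library profiled H2A.Z in wild-type primary dermal fibroblasts from newborn females. Directional poly(A) RNA-seq had 3 replicates at 0h, 6h and 24h. The input library was not used here.

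Per the labels, the authors aligned ChIP reads with Bowtie 1.1.2 to GRCm38 and called broad regions with SICER 1.1, and aligned RNA reads with STAR 2.5.2b. The deposited RNA values are raw counts per gene without normalization. The deposited region lists carry a whole-number score per region, whose reference the labels do not state, and another column (unit: other) with a running number that is not a measurement. The region calls used here had a window of 200 bases, a gap of 800 bases and a caller threshold of 0.01, and the 5d library was also read with a window of 1000 and a gap of 4000. Gene positions were those of RefSeq GRCm38.p6.

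RNA counts were taken from the strand column that held 96.6% or more of stranded counts in each library (column 4). Libraries held 29338093 to 37793178 counts over genes, and 21.2 to 23.1% of reads were unmapped, mapped to more than 1 place or not assigned to 1 gene. All 9 libraries were fitted together with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, glmQLFit and glmQLFTest, time group only), which kept 13785 genes, with a biological coefficient of variation of 2.69%. P values were adjusted by Benjamini-Hochberg within each contrast, and genes with adjusted p under 0.05 were called, without a fold threshold. CPM are normalised with TMM for RNA values and plain for the expression classes and named ChIP genes. Of 27 gene lists, the 24 with 5 or more tested members were tested with camera (limma 3.58.1) on log CPM with a prior count of 2 and a preset correlation of 0.01. Their p values were adjusted over the lists of a contrast and repeated with an estimated correlation. Of the calls, only cholesterol biosynthesis at 6h and from 6h to 24h held with an estimated correlation. Some lists overlap, since Dcn and Col1a1 are each members of more than 1 list.

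Named RNA genes were, per contrast, the 10 protein-coding genes with the largest increase and the 10 with the largest decrease among those called, with a mean of 1 CPM or more and no overlap between the groups' libraries, the H2A variant list, and up to 4 members with the smallest p of each list called or with 3 or more called members. Markers of other cell types that were called are named too, which was decided after their values were seen. Named ChIP genes had 80% or more coverage at 6h and 20% or less at 24h and 5d (10 highest by CPM), 80% or more at 6h, 24h and 5d (10 longest, 5 highest by CPM), 20% or less at 24h and 80% or more with flavopiridol (10 highest by CPM), or a difference of 60 points with GSK126 (5 longest each way), besides H2afy2, H2afy and the 5 developmental genes with the highest coverage at 5d. A few genes that these rules select are not reported here.

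Regions were merged per library with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 on chromosomes 1 to 19, X and Y (2722 Mb). Y took 90.8 Mb of this, and regions covered 0.0718% of it at 24h, so it raises the ratios to independence. Gene bodies were examined on chromosomes 1 to 19 and X (20 chromosomes). Gene body coverage is the percent of bases inside regions for 18415 protein-coding genes of 3 kb or more, 1 kb trimmed at both ends because the gene table was used without strand. Of these, 17970 had RNA counts and were classed by mean CPM at 0h as silent (under 0.1), low (0.1 to 1), medium (1 to 10) or high (10 or more). CPM took the place of the RPKM that had been planned for the classes and for ranking named ChIP genes, since exon lengths were not used. The plan had been to trim only the start of each gene. Overlaps were compared with the share under independence over the chromosomes. Coverage of gene lists was compared with 10000 random lists matched in 20 groups of expression, but not on gene length or chromosome. Intervals of shares of genes are exact Clopper-Pearson intervals at 95% from scipy 1.17.1 and cover counting error over genes only. The read depth behind each region is unknown. With 1 library per condition no test between ChIP conditions was made. Differences are also described per chromosome. The chromosomes of a library share its depth and region calling, so they are not replicates. Sets of genes from the regions were tested with camera over 11122 genes. Figures were drawn with matplotlib 3.10.9.

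The RNA test was tested on simulated data of the same depth, where it recovered 86% of 50 genes changed 1.25-fold at 6h and 84% at 24h, 100% of those changed 2-fold, and called at most 0.0596% of unchanged genes. Gene body coverage was checked base by base in 400 genes, with 0 differing. The replicate numbers did not pair libraries, since residual correlations between libraries of the same number were -0.0183 to 0.0390 and between others -0.0623 to 0.0521. Between replicates of a group, chi-square per gene was 2.06 to 9.03.

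Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, unstranded counts, only the 6 libraries of a contrast, the replicate number as a block, leaving out each library in turn, an estimated set correlation, 80% in place of 50% coverage, regions with the best scores, the wider window at 5d, 50% of a region in place of 1 base for overlaps, only 1 kb bins touched by any library, whole genes, genes of 20 kb or more, and regions of 2 kb or longer. Leaving out chromosomes 8, 15 and 17, and using H2A.Z regions of score 3 or more, were added after seeing the data. Scaling moved the median change of all genes by less than 0.1 on the log2 scale in each contrast.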

Results

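Expression of macroH2A2, a histone H2A variant with a large globular macro domain, was switched on with doxycycline in immortalized mouse dermal fibroblasts labelled as lacking both macroH2A1 and macroH2A2. Poly(A) RNA was counted at 0h, 6h and 24h in 3 replicate libraries each, with 29338093 to 37793178 counts over genes per library. Regions called for macroH2A2-GFP came from 1 native ChIP-seq library per condition, so every difference between ChIP conditions is a description of those libraries without a test. Log2 changes are from the quasi-likelihood test of edgeR with adjusted p over 13785 genes, errors of CPM means are SD with n = 3, and list tests are camera with a fixed correlation. For lists given with 1 pair of counts, the counts adjusted over the list alone were the same.

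The gene of the induced variant, H2afy2 (ENSMUSG00000020086, chromosome 10, 61738640 to 61784604, RefSeq GRCm38.p6), had the largest change in RNA at both times. H2afy2 stood at 15.1 ± 8.80 CPM at 0h, where the 3 libraries held 10.5, 25.3 and 9.61, and rose to 820.2 ± 14.3 CPM at 6h and 1727 ± 13.8 CPM at 24h. Its log2 change was 5.77 ± 0.14 (SE) at 6h, 6.84 ± 0.14 at 24h and 1.07 ± 0.10 from 6h to 24h. The cells carried a macroH2A2-GFP transgene, and counts for H2afy2 do not separate its RNA from that of the gene on chromosome 10. H2afy, the gene of macroH2A1, was not called in any contrast and had mean levels of 56.8, 56.9 and 57.0 CPM at 0h, 6h and 24h, with 51.5 to 60.6 CPM in the 9 libraries. RNA of both genes was thus counted at 0h in cells labelled as lacking both proteins. Counts are sums over whole genes and the deleted parts were not examined here, so they do not settle whether the label holds. H2afy3, annotated as a transcribed pseudogene and named here after its values were seen, rose from 0.0693 CPM at 0h to 2.24 at 6h and 4.95 at 24h, log2 changes of 4.96 ± 0.33 (SE) and 6.09 ± 0.28. From 6h to 24h H2afy3 changed by 1.13 ± 0.14, near the 1.07 of H2afy2. Whether its counts were reads of the transgene was not tested, so its rise may not be that of a separate gene. H2afv, which encodes a form of H2A.Z, fell by 0.36 on the log2 scale at 6h (SE 0.039) and rose by 0.44 from 6h to 24h (SE 0.038), while H2afz, the main H2A.Z gene, rose by 0.14 at 24h (SE 0.027). H2afx fell by 0.13 on the log2 scale at 24h (SE 0.032). It was not called without 0h replicate 2 (log2 change -0.12, adjusted p = 0.0679), 0h replicate 3 (-0.12, 0.0530) or 24h replicate 2 (-0.081, 0.171). From 6h to 24h it was not called, but passed without 6h replicate 2 (0.0477) or 24h replicate 1 (0.00372) and with unstranded counts (0.0398). H2afj was not called in any contrast, but passed at 6h without 6h replicate 1 (0.0238) and from 6h to 24h without 6h replicate 1 (0.0101) or 24h replicate 2 (0.0359). As a list, these 6 genes were not called at 6h (median -0.020, mean 0.89 through H2afy2, adjusted p = 0.923), at 24h (adjusted p = 0.0526, but 0.0275 with unstranded counts) or from 6h to 24h (adjusted p = 0.144).

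After 6h of doxycycline, the largest increases besides H2afy2 among protein-coding genes with a mean of 1 CPM or more included genes of secreted and matrix proteins. Serpinb2, which encodes plasminogen activator inhibitor 2 (ENSMUSG00000062345, chromosome 1, 107500892 to 107525600), rose from 4.11 ± 0.884 to 38.4 ± 2.29 CPM, a log2 change of 3.23 (SE 0.087, adjusted p = 1.9e-21). Gjb2, the connexin 26 gene, changed by 2.18 (SE 0.15, adjusted p = 2.4e-12), Aldh1a3, a retinaldehyde dehydrogenase gene, by 1.84 (SE 0.25, adjusted p = 7.8e-07), and Postn, the gene of the matrix protein periostin, by 1.52 (SE 0.063, adjusted p = 3.6e-17). Has2, which encodes a hyaluronan synthase, rose from 54.7 ± 1.47 to 151 ± 8.03 CPM. Fibcd1, Olfm2, Lad1 and Mylk2 completed the 10 largest increases among these genes, at log2 1.54, 1.52, 1.34 and 1.33. Among the largest decreases under the same rule were Hlf, which encodes a circadian output transcription factor (from 16.7 ± 0.659 to 6.99 ± 0.451 CPM), and Per2, a repressor of the circadian clock (-1.20, SE 0.10, adjusted p = 2.6e-10). Gas1, a growth arrest gene, fell from 55.9 ± 4.69 to 24.0 ± 2.82 CPM, and Ccn5, which encodes a matricellular protein, fell from 5.44 ± 0.362 to 2.33 ± 0.302 CPM. Gbp2b, Ranbp3l, Hacd4, Glt8d2, Adra1d and Synpo fell by 1.08 to 1.34 on the log2 scale. Across all genes, 2868 rose and 2509 fell (39.0% of those tested). Of these, 201 rose and 241 fell by 1.5-fold or more, and the median size of the called changes was 0.20 on the log2 scale.

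**Figure D1:**
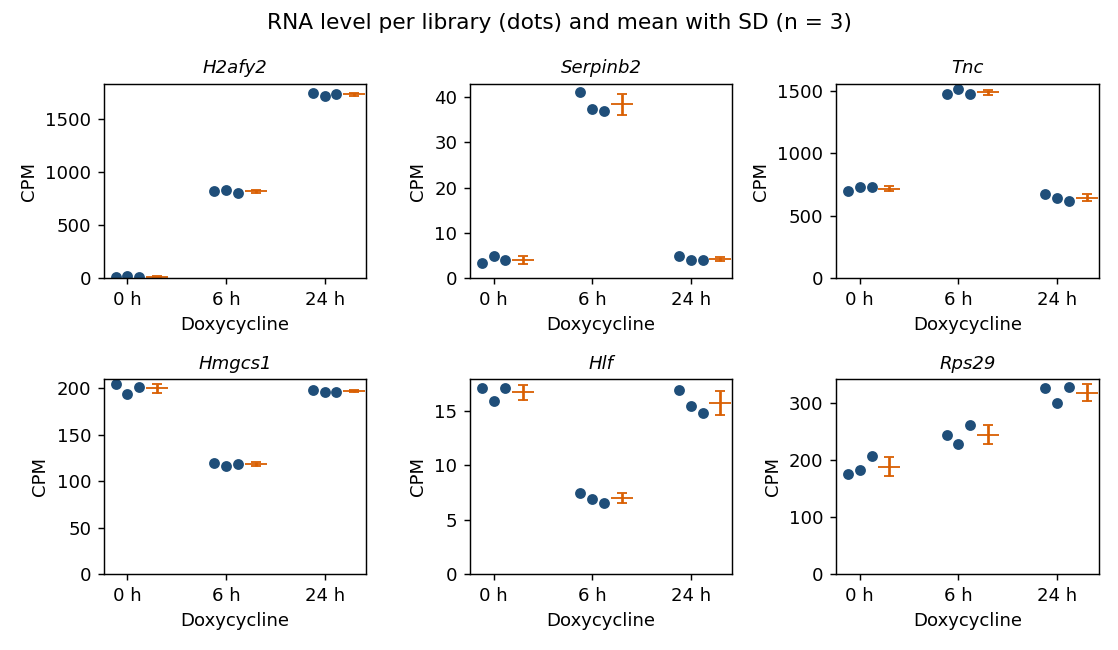
Normalised expression (CPM, linear scale) of 6 genes in the 9 RNA libraries at 0h, 6h and 24h of doxycycline, with points for replicates and bars for mean and SD. H2afy2 reaches 1727 CPM at 24h, while Serpinb2, Tnc, Hmgcs1 and Hlf move at 6h and lie near their 0h level at 24h, and Rps29 is highest at 24h.

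Cholesterol biosynthesis genes fell together at 6h, as 0 of 24 rose and 23 fell, and 0 rose and 24 fell adjusted over the list alone. Their median log2 change was -0.45 (adjusted p = 4.6e-15, and 0.0356 with an estimated correlation). Hmgcs1, which encodes the HMG-CoA synthase of the pathway, fell by 0.76 on the log2 scale, Insig1, the gene of an ER protein that restrains SREBP processing, by 0.87 and Cyp51 by 0.51. Of the genes for the mitochondrial ribosome and mitochondrial chaperones, 24 of 29 rose and 5 did not pass (adjusted p = 4.0e-06, and 0.211 with an estimated correlation), with Hspd1 at 0.36, Mrpl1 at 0.30 and Hspa9 at 0.22. In the integrated stress response, a programme driven by the transcription factor ATF4, 21 of 33 rose and 2 fell, and 23 rose and 2 fell adjusted over the list alone (adjusted p = 9.2e-06, and 0.0923 with an estimated correlation). There Slc7a11, a cystine transporter gene, rose by 0.64, Nars by 0.32, Mthfd2 by 0.32 and Atf4 itself by 0.26. Among heat shock and ER chaperone genes 20 of 30 rose and 4 fell, and 20 rose and 6 fell adjusted over the list alone (adjusted p = 3.3e-04, and 0.253 with an estimated correlation), with Hspa5, which encodes the chaperone BiP, at 0.61 and Hyou1 at 0.40. Of the ribosomal protein and translation housekeeping genes 20 of 36 rose and 2 fell, and 20 rose and 3 fell adjusted over the list alone (adjusted p = 5.9e-04, and 0.504 with an estimated correlation), with Rpl37 at 0.31 and Rpl32 at 0.28.

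Genes responsive to TGF-beta and YAP signalling rose at 6h, as 15 of 27 rose and 5 fell (adjusted p = 0.00346, and 0.456 with an estimated correlation). Among them Tagln rose by 0.83, Ltbp2 by 0.70 and Acta2, the smooth muscle actin gene, by 0.54. Fibroblast markers went the other way, as 2 of 18 rose and 10 fell, and 2 rose and 11 fell adjusted over the list alone (adjusted p = 0.0112, and 0.266 with an estimated correlation), among them Prrx2 at -0.69, Pdgfrb at -0.47 and S100a4 at -0.29, while Thy1 rose by 0.33. Of the developmental transcription factor genes 3 of 45 rose and 13 fell (adjusted p = 0.0251, and 0.156 with an estimated correlation). Hoxc9 fell by 0.43, Hoxc6 by 0.31 and Hoxb9 by 0.21 on the log2 scale, and Sox9 rose by 0.74.

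Collagen and other matrix genes moved both ways at 6h and were not called as a list (16 of 33 rose and 10 fell, adjusted p = 0.127), with Tnc, the tenascin C gene, at 1.05 and Timp1 at 0.96. Immediate early genes were not called (12 of 28 rose and 8 fell, and 13 rose and 8 fell adjusted over the list alone, adjusted p = 0.264), with Dusp5 at 1.11, Fosl1 at 0.61 and Dusp1 at -0.40. Of the histone chaperones and remodellers 12 of 24 rose and 3 fell (adjusted p = 0.108), with the nucleolar genes Npm1 at 0.43 and Ncl at 0.36. In the Polycomb group 2 of 24 rose and 9 fell (adjusted p = 0.127), with Phf1 at -0.42, Ezh1 at -0.34 and Ezh2, the target of GSK126, at 0.16. Of the inflammatory and secretory genes 9 of 18 rose and 3 fell (adjusted p = 0.108), and of the interferon response genes 1 of 18 rose and 4 fell (adjusted p = 0.654). Among mitochondrially encoded genes 6 of 9 rose and 0 fell, and 6 rose and 1 fell adjusted over the list alone (adjusted p = 0.127), and among nuclear respiratory chain genes 15 of 45 rose and 6 fell, and 16 rose and 6 fell adjusted over the list alone (adjusted p = 0.127). Glycolysis and hypoxia genes were split, as 8 of 29 rose and 6 fell, and 8 rose and 7 fell adjusted over the list alone (adjusted p = 0.899), Vegfa at 0.62 and Pfkfb3 at 0.66, and their median of 0.0033 turned negative with RLE scaling (-0.0027).

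Targets of p53 were split at 6h as well, as 8 of 24 rose and 8 fell, and 9 rose and 8 fell adjusted over the list alone. They had a median of 0.059, a mean of -0.010 and a list test pointing down (adjusted p = 0.930). For the G1/S cell cycle genes 11 of 45 rose and 4 fell (adjusted p = 0.331), with Rrm2 at 0.20, and for the G2/M genes 4 of 50 rose and 9 fell (adjusted p = 0.468), with Ccnb2 at -0.33. Among 24 core histone genes edgeR called none, at adjusted p or at an unadjusted p under 0.05, and DESeq2 called none (list adjusted p = 0.869). The list of core histone genes also names linker histone genes. Some markers of other cell types moved with the changes of 6h. Itga6 rose by 0.32 from 211 to 263 CPM, Flt1 by 0.27 from 24.9 to 29.9 CPM, and Acta1, the skeletal muscle actin gene, by 1.31 from 4.77 to 11.8 CPM. Epcam rose to 2.57 CPM and Mrc1 to 1.05 CPM, both near the lower end of the tested genes, and Notch3 changed by -0.41. Keratinocyte markers (2 of 5 rose and 0 fell, adjusted p = 0.127) and endothelial and mural markers (1 of 6 rose and 1 fell, adjusted p = 0.899) were not called as lists. With 4 tested members each, too few for a list test, 1 macrophage marker (Mrc1) and 1 adipocyte or muscle marker (Acta1) rose, and edgeR called no melanocyte or Schwann marker, at adjusted p or at an unadjusted p under 0.05, as did DESeq2.

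At 24h the largest increases after H2afy2 among protein-coding genes with a mean of 1 CPM or more included genes of ribosomal proteins and of the mitochondrial ATP synthase. Rps29, which encodes a protein of the small ribosomal subunit (ENSMUSG00000034892, chromosome 12, 69157722 to 69159186), rose from 188 ± 16.2 to 318 ± 15.2 CPM, a log2 change of 0.76 (SE 0.044, adjusted p = 2.1e-12). Atp5k changed by 0.76 (SE 0.060, adjusted p = 1.1e-09) and Atp5g2 by 0.65 (SE 0.080, adjusted p = 2.5e-06), both genes of ATP synthase subunits. Rpl29 rose by 0.61 ± 0.087, Rpl35 by 0.61 ± 0.060 and Mrps21, a mitochondrial ribosome gene, by 0.54 ± 0.075 (SE). Among the decreases, Fosb, an AP-1 subunit gene, changed by -0.45 (SE 0.11, adjusted p = 0.00706), Hic1, a transcriptional repressor gene, by -0.36 (SE 0.060, adjusted p = 2.0e-04), and Jund by -0.35 (SE 0.044, adjusted p = 2.7e-06). Jund changed by -0.15 with unstranded counts and was not called (adjusted p = 0.0621, range over the alternatives 4.1e-24 to 0.0621). Across all genes 575 rose and 396 fell (7.04% of those tested). Of these, 33 rose and 6 fell by 1.5-fold or more. By 2-fold or more 12 rose, of which 9 had a mean under 1 CPM and the others were H2afy2, H2afy3 and Rn7sk, the gene of the 7SK RNA. The count of 971 called genes dropped to 647 without 0h replicate 1, 553 without 0h replicate 2, 631 without 24h replicate 2 and 629 without 24h replicate 3.

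Of the 20 genes that the rule selects for the largest changes at 24h, 9 lost their call without 1 library. Aspn, the gene of the matrix proteoglycan asporin, fell by 0.93 on the log2 scale but not without 24h replicate 3 (adjusted p = 0.110) or with unstranded counts (0.0566, range over the alternatives 5.8e-05 to 0.110). Fos fell by 0.59 but not without 0h replicate 1 or 24h replicate 2 (range 1.5e-04 to 0.0810). Dcn, the decorin gene, changed by -0.68 and passed without 1 library only when that library was 0h replicate 2. With only the 6 libraries of the contrast it also changed by -0.68 but was not called (adjusted p = 0.0597, range 0.0151 to 0.257). Zfp174 at -0.76 was lost without 0h replicate 1, 0h replicate 2 or 24h replicate 1 (highest adjusted p 0.116), and Zfp970 at -0.49 without 0h replicate 1, 24h replicate 1 or 24h replicate 2 (0.230). Spata5l1 at -0.47 was lost without 0h replicates 1 or 3 or 24h replicates 1 or 3 (0.105), and Zfp971 at -0.39 without 0h replicates 2 or 3 or 24h replicates 1 or 3 (0.141). DESeq2 called neither (adjusted p = 0.0789 and 0.0765). Mrps36 at 0.71 was lost without 0h replicates 1 or 2, 6h replicates 1 or 3 or 24h replicate 3 (0.340), and B230307C23Rik at 0.62 without any 0h replicate or 24h replicates 1 or 2 (0.184). The former was also lost with only the 6 libraries (adjusted p = 0.0503) and the latter with unstranded counts (0.0563). Ccdc73 at 1.00 was called without each library in turn but changed by 0.40 with unstranded counts and was not called (adjusted p = 0.0591, range 2.0e-05 to 0.0591).

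Nuclear respiratory chain genes rose as a group at 24h, with 26 of 45 called up and the other 19 not passing, and 32 called up adjusted over the list alone (adjusted p = 6.0e-16, and 0.269 with an estimated correlation). Ndufa1, Ndufa2 and Ndufb9, genes of complex I subunits, changed by 0.45, 0.35 and 0.25, and Cox7b of complex IV by 0.24. Reads outside genes were 6.35 to 7.00% of all reads in the 24h libraries, against 5.97 to 6.05% at 0h and 5.68 to 6.23% at 6h. Reads not counted for any gene, unmapped ones included, were 22.8 to 23.1% against 21.2 to 22.1% and 21.5 to 22.2%, so this share was higher along with these genes and those of ribosomal proteins. Of the ribosomal protein and translation housekeeping genes 23 of 36 rose and 13 did not pass, and adjusted over the list alone 26 rose and 2 fell (adjusted p = 2.5e-13, and 0.269 with an estimated correlation), with Rpl37 at 0.43, Rps23 at 0.41 and Rpl32 at 0.35. Of the mitochondrial ribosome and chaperone genes 4 of 29 rose and 25 did not pass (adjusted p = 0.0137, and 0.458 with an estimated correlation), among them Mrpl16 at 0.21. Among mitochondrially encoded genes 5 of 9 rose, and adjusted over the list alone 5 rose and 2 fell (adjusted p = 0.0496, and 0.670 with an estimated correlation). With unstranded counts the list was not called (adjusted p = 0.237). There mt-Rnr2 rose by 0.14 and mt-Rnr1 by 0.15, and mt-Nd6, the gene on the light strand, rose by 0.24 but changed by -0.088 with unstranded counts.

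**Figure D2:**
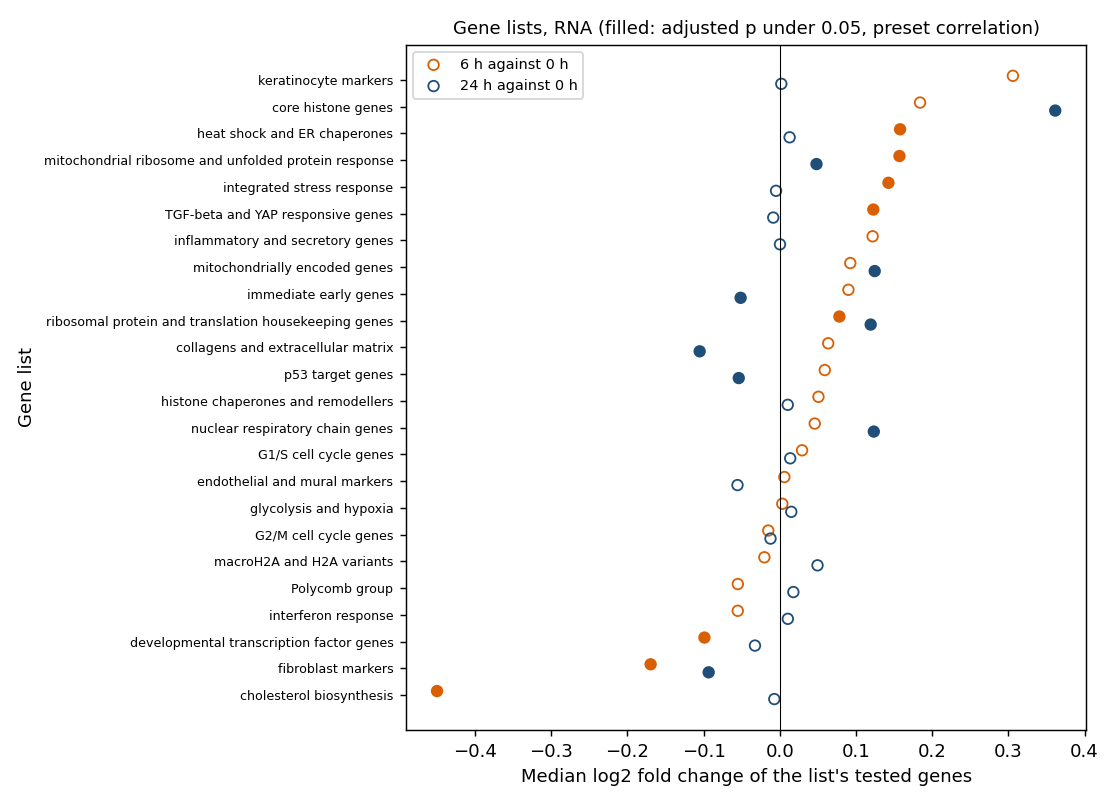
Median log2 fold change of each gene list with 5 or more tested genes, for 6h and 24h against 0h, with filled points for lists called at adjusted p under 0.05 by camera with a correlation of 0.01. Cholesterol biosynthesis lies at -0.45 at 6h, and the nuclear respiratory chain and ribosomal lists lie at 0.12 and 0.12 at 24h.

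Matrix genes fell at 24h, as 2 of 33 rose and 18 fell, and 2 rose and 20 fell adjusted over the list alone among collagens and other matrix genes (adjusted p = 8.0e-08, and 0.269 with an estimated correlation). Col1a1, a chain of type I collagen, fell by 0.19, Col5a1 by 0.16 and Loxl1 by 0.16 on the log2 scale, while Col5a2 rose by 0.18. Of the fibroblast markers 2 of 18 rose and 4 fell, and 2 rose and 9 fell adjusted over the list alone (adjusted p = 0.0171, and 0.332 with an estimated correlation), with Pdgfrb at -0.15 and Thy1 at 0.16. Immediate early genes fell in 5 of 28 cases and 23 did not pass, with 9 down adjusted over the list alone (adjusted p = 0.00291, and 0.269 with an estimated correlation), among them Junb at -0.26. Of the p53 targets 5 of 24 fell and 19 did not pass, with 7 down adjusted over the list alone (adjusted p = 0.0137, and 0.573 with an estimated correlation), among them Trp53inp1 at -0.31 and Ccng1 at -0.14. Core histone genes had a median log2 change of 0.36 and were called as a list (adjusted p = 0.0496, and 0.634 with an estimated correlation), though edgeR and DESeq2 each called 0 of 24 members and edgeR gave 2 an unadjusted p under 0.05. With unstranded counts the list was not called (adjusted p = 0.102). The RNA was selected by poly(A), and whether these transcripts carry poly(A) tails was not examined.

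Several lists that were called at 6h were not called at 24h. For cholesterol biosynthesis 0 of 24 rose and 1 fell (median -0.0072, mean 0.0050, test pointing down, adjusted p = 0.501), and for the integrated stress response 3 of 33 rose and 1 fell (median -0.0049, mean 0.00090, test pointing down, adjusted p = 0.961). Of the TGF-beta and YAP responsive genes 1 of 27 rose and 4 fell (adjusted p = 0.484), of the heat shock and ER chaperones 1 of 30 rose and 0 fell (adjusted p = 0.269), and of the developmental transcription factor genes 0 of 45 rose and 2 fell, and 0 rose and 1 fell adjusted over the list alone (adjusted p = 0.141). Lists called at neither 6h nor 24h were the following. In G1/S 3 of 45 rose and 0 fell (adjusted p = 0.336), and in G2/M 2 of 50 rose and 2 fell, and 2 rose and 3 fell adjusted over the list alone (adjusted p = 0.484), with Cks2 at 0.23. Of the chaperones and remodellers 1 of 24 rose and 0 fell (adjusted p = 0.796), and of the glycolysis and hypoxia genes 1 of 29 rose and 0 fell (adjusted p = 0.336). For inflammatory genes 1 of 18 rose and 1 fell, and 1 rose and 2 fell adjusted over the list alone (adjusted p = 0.517) and for interferon response genes 1 of 18 rose and 0 fell (adjusted p = 0.611), and the medians of both, 0.00027 and 0.011, turned negative with DESeq2 scaling, to -0.0032 and -0.0031. The inflammatory list also had a mean of -0.033.

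Polycomb group genes showed no call at 24h with edgeR or DESeq2 (0 of 24), with 2 up and 2 down at an unadjusted p under 0.05 in edgeR, a median of 0.018, a mean of -0.0049 and a list test pointing down (adjusted p = 0.862). Of the 5 tested keratinocyte markers neither tool called any, with 0 at an unadjusted p under 0.05, a median of 0.0020 that turned negative with RLE scaling (-0.00094), a mean of -0.018 and a test pointing up (adjusted p = 0.523). Of the endothelial and mural markers 0 of 6 rose and 1 fell (adjusted p = 0.135), the decrease being Cspg4 at -0.19. Of 4 tested macrophage, 4 melanocyte or Schwann and 4 adipocyte or muscle markers, edgeR and DESeq2 called 0 over all genes. At an unadjusted p under 0.05 edgeR gave 1 macrophage marker up, 0 melanocyte markers and 1 adipocyte or muscle marker down, and adjusted over the list alone 1 macrophage marker rose and 1 adipocyte or muscle marker fell.

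Between 6h and 24h the largest changes included genes that had changed in the other direction at 6h. Serpinb2 fell from 38.4 ± 2.29 to 4.34 ± 0.482 CPM, a log2 change of -3.14 (SE 0.086, adjusted p = 3.3e-21), against 4.11 CPM at 0h. Gjb2, Olfm2, Postn and Aldh1a3 fell by 1.97, 1.89, 1.68 and 1.62 on the log2 scale, and Fibcd1, Lad1, Acta1, Mylk2 and Smoc2 by 1.51 to 1.68. In the other direction Hlf rose by 1.17 ± 0.075 (SE), Per2 by 1.09 ± 0.11 and Dbp, another circadian output gene, by 1.02 ± 0.13. Hacd4, Glt8d2, Ppl, Ccn5, Lipg and Lpin1 rose by 1.02 to 1.34. In all 2395 genes rose and 2585 fell (36.1%). Of the 201 genes up by 1.5-fold or more at 6h, 177 were not called at 24h against 0h, 16 were still up and 8 were down, and their median log2 change went from 0.87 to 0.12. Of the 241 genes down by 1.5-fold or more, 227 were not called at 24h and 14 were still down, with medians of -0.80 and -0.11. These genes were chosen on the 6h libraries, so part of the shift toward 0 may come from the choice.

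List tests of 24h against 6h share the 6h libraries with 6h against 0h. A list that reverses its change of 6h, here or in the next paragraph, is thus not a separate result. Cholesterol biosynthesis genes all rose from 6h to 24h (24 of 24, adjusted p = 6.4e-16, and 0.0308 with an estimated correlation), with Hmgcs1 at 0.73 and Insig1 at 0.79. Nuclear respiratory chain genes rose as well, as 22 of 45 rose and 1 fell (adjusted p = 3.0e-04, and 0.405 with an estimated correlation), among them Ndufa1 at 0.35. In the integrated stress response 4 of 33 rose and 22 fell (adjusted p = 7.0e-06, and 0.0815 with an estimated correlation), with Slc7a11 at -0.66 and Ddit3 at -0.59. Of the TGF-beta and YAP responsive genes 3 of 27 rose and 15 fell, and 4 rose and 15 fell adjusted over the list alone (adjusted p = 3.0e-04, and 0.287 with an estimated correlation), with Tagln at -0.72 and Ltbp2 at -0.90. For collagens and extracellular matrix 9 of 33 rose and 21 fell, and 9 rose and 22 fell adjusted over the list alone (adjusted p = 3.0e-04, and 0.220 with an estimated correlation), with Tnc at -1.20 and Timp1 at -0.79. Among heat shock and ER chaperones 4 of 30 rose and 17 fell (adjusted p = 3.0e-04, and 0.220 with an estimated correlation), with Hspa5 at -0.61. Mitochondrial ribosome and chaperone genes moved down, as 1 of 29 rose and 13 fell, and 1 rose and 14 fell adjusted over the list alone (adjusted p = 2.4e-04, and 0.220 with an estimated correlation), and Hspd1 at -0.27. Of the immediate early genes 5 of 28 rose and 17 fell (adjusted p = 0.0140, and 0.220 with an estimated correlation), with Dusp5 at -1.10 and Dusp1 at 0.47.

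Further shifts from 6h to 24h were called for the histone chaperones and remodellers (1 of 24 rose and 9 fell, and 1 rose and 10 fell adjusted over the list alone, adjusted p = 0.0394, and 0.220 with an estimated correlation), with Ncl at -0.36 and Npm1 at -0.30, and for the inflammatory genes (5 of 18 rose and 10 fell, adjusted p = 0.0394, and 0.220 with an estimated correlation), with Hmga2 at -0.43. Lists that were not called were the Polycomb group (7 of 24 rose and 3 fell, adjusted p = 0.203, Phf1 at 0.45), mitochondrially encoded genes (2 of 9 rose and 1 fell, adjusted p = 0.881), interferon response (4 of 18 rose and 2 fell, adjusted p = 0.285, Ifit1 at -1.24) and p53 targets (4 of 24 rose and 10 fell, and 5 rose and 10 fell adjusted over the list alone, adjusted p = 0.271, Plk2 at 0.55). Of the glycolysis and hypoxia genes 8 of 29 rose and 7 fell, and 9 rose and 7 fell adjusted over the list alone, with a median of 0.029, a mean of -0.010 and a test pointing up (adjusted p = 0.784). For fibroblast markers 8 of 18 rose and 4 fell (adjusted p = 0.285, Prrx2 at 0.52), for developmental transcription factors 10 of 45 rose and 2 fell (adjusted p = 0.144, Sox9 at -0.83), and for ribosomal genes 11 of 36 rose and 3 fell (adjusted p = 0.123). Of the G1/S genes 8 of 45 rose and 10 fell (adjusted p = 0.565), of the G2/M genes 8 of 50 rose and 6 fell, and 7 rose and 6 fell adjusted over the list alone (adjusted p = 0.744), of the keratinocyte markers 0 of 5 rose and 2 fell (adjusted p = 0.203), and of the endothelial and mural markers 0 of 6 rose and 2 fell (adjusted p = 0.273). Of 24 core histone genes edgeR and DESeq2 called 0, with 1 up at an unadjusted p under 0.05 (list adjusted p = 0.313), and of the macrophage and melanocyte markers both tools called 0, with 1 macrophage marker down at an unadjusted p under 0.05. Of the 4 adipocyte and muscle markers, Acta1 fell, to 3.78 CPM.

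Some genes were called at both 6h and 24h. Against the same 0h libraries, 361 genes rose and 228 fell at both times, and 56 rose at 6h and fell at 24h while 26 did the reverse. Lists drawn independently would share 119.6 and 72.1 genes, and 10 simulations with unchanged genes and the 0h libraries shared gave at most 1 and 0. The simulations leave out real effects and the independent lists leave out the shared libraries, so neither measures a shared effect, and part of the excess may come from the shared 0h libraries. Across genes, the covariance of the 6h and 24h changes was 0.0249 against a mean of 0.0119 in the simulations, where the shared 0h libraries alone gave a correlation of 0.491 (0.403 in the data). Genes are not independent replicates, so these values carry no p. They include H2afy2 and H2afy3, which the simulations left unchanged, so part of the excess in covariance comes from these genes.

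Regions were already called in the macroH2A2-GFP library at 0h, before doxycycline, where 28980 regions covered 201 Mb. No GFP-Trap library came from cells without the transgene, so whether the 0h regions held macroH2A2-GFP was not tested. At 0h 69.9% of the regions had the lowest score, against 48.3% at 6h, and those with better scores covered 51.4 Mb at 0h and 203 Mb at 6h. In all there were 62192 regions over 383 Mb at 6h, 44827 over 363 Mb at 24h and 48386 over 351 Mb at 5d, so the 6h regions were more numerous and narrower, with median widths of 4.40 kb at 6h and 5.20 kb at 24h. Of the bases covered at 0h, 89.4% lay inside the 24h regions and 88.7% inside the 5d regions. Of the 24h bases 64.5% were covered at 6h, 4.59 times the share under independence, and 76.5% of the 24h regions touched a 6h region. Of the 5d bases 78.1% were covered at 24h (5.86 times independence, 81.5% of regions) and 50.8% at 0h (6.88 times, 51.0%). The read depth of these libraries was not used here, and region counts move with depth.

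Bodies of highly expressed genes had a higher mean coverage at 6h than at 24h. Over 8421 protein-coding genes with 10 CPM or more at 0h, mean body coverage was 0.942% at 0h, 20.1% at 6h, 2.27% at 24h and 1.17% at 5d. The 24h value was lower than the 6h value on all 20 chromosomes examined, a difference of -17.8 percentage points in the mean. The chromosomes of a library share its depth, so they do not replicate this difference. At 6h the median of these genes was 6.77%, and 15.3% of them had 50% or more covered. Silent genes, 6308 with under 0.1 CPM, went the other way, from 8.30% at 0h and 10.0% at 6h to 17.2% at 24h, higher than at 6h on 20 of 20 chromosomes, and 15.4% at 5d. Genes of 0.1 to 1 CPM (1326 genes) were at 13.1%, 24.4%, 29.8% and 22.9%, higher at 24h than at 6h, and those of 1 to 10 CPM (1915 genes) at 6.06%, 20.5%, 14.1% and 8.69% at 0h, 6h, 24h and 5d. In the low class the difference of 5d minus 6h was -1.53 points, but 3.61 points in genes of 20 kb or more. With the wider window, silent, low, medium and high genes were at 26.4%, 37.0%, 15.6% and 1.94% at 5d. Relative to silent genes of the same library, high genes were covered 0.114 times as much at 0h, 2.01 times at 6h, 0.132 times at 24h and 0.0761 times at 5d. In 10 groups of expressed genes ranked by expression, the highest (median 291 CPM) had a coverage of 24.7% at 6h and 1.26% at 24h, and the lowest (median 0.277 CPM) of 24.2% and 30.0%.

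**Figure D3:**
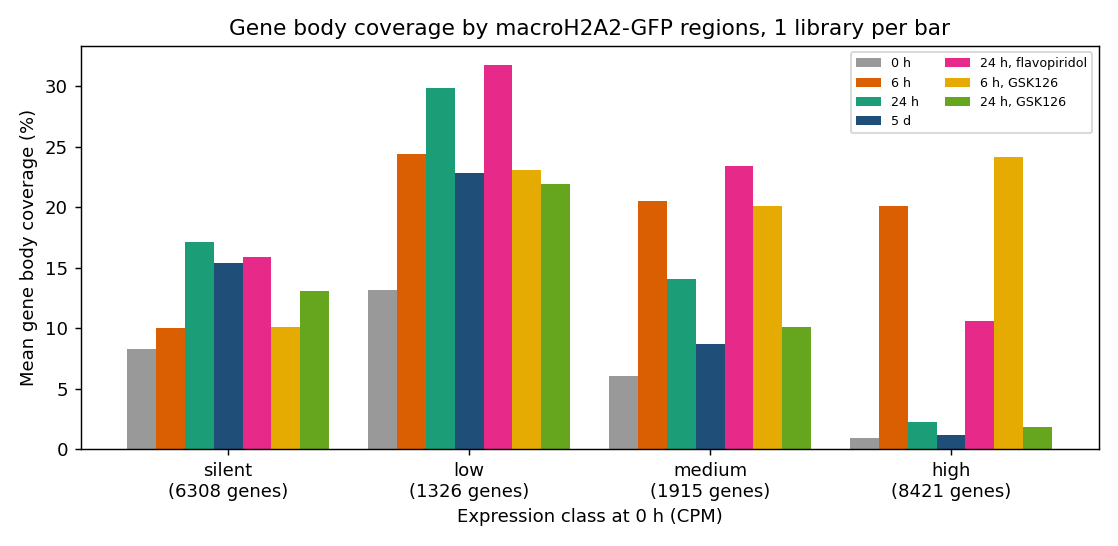
Mean percent of gene body bases inside macroH2A2 regions for silent, low, medium and high expression classes (0h RNA), 1 library per condition. High genes are at 20.1% at 6h, 2.27% at 24h and 10.6% at 24h with flavopiridol.

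**Figure D4:**
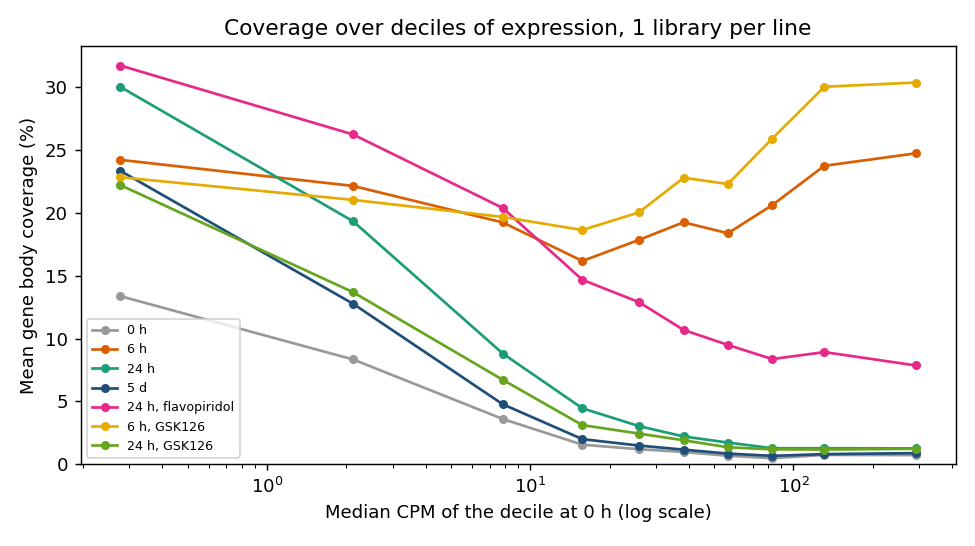
Mean percent of gene body bases inside macroH2A2 regions against the median 0h CPM (log scale) of 10 groups of expressed genes ranked by expression, 1 line per library. At 291 CPM the 6h line stands at 24.7% and the 24h line at 1.26%.

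Of 1289 high genes with 50% or more of the body covered at 6h, 1059 had under 10% covered at 24h, 82.2% (95% exact Clopper-Pearson interval 80.0 to 84.2), and 64 still had 50% or more. At 0h 23 of these genes had 50% or more, and at 5d 1169 had under 10%. Of 472 silent genes covered to 50% or more at 6h, 395 were still so at 24h, 83.7% (95% exact Clopper-Pearson interval 80.0 to 86.9), and 240 were so at 0h. Itgb1, the integrin beta 1 gene (ENSMUSG00000025809, chromosome 8, 128685654 to 128733579) with 2137 CPM, had 95.8% of its body covered at 6h and 0% at 0h, 24h and 5d. Cbx5, which encodes the heterochromatin protein HP1 alpha, went from 0% at 0h to 81.5% at 6h and 4.31% at 24h. Of the 413 genes with 80% or more at 6h and 20% or less at 24h and 5d, the 10 with the highest expression (Itgb1, Cbx5, Tcp1, Abce1, Cpe, Qk, St13, Hnrnpm, Cnot1 and Ddx17) all lie on chromosomes 8, 15 and 17, and 148 of the genes lie elsewhere.

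A further 172 genes had 80% or more of the body covered at 6h, 24h and 5d, 82 of them outside chromosomes 8, 15 and 17. The longest were Rcan2 (238 kb), Cubn, Ptprq, Tg, Adamts18, Fyb, Smoc2, Myom1, Hormad2 and Musk, with 0h CPM between 0 and 21.8. Before doxycycline these genes and the 5 with the highest expression were covered to 47.6% or more. Tg, the thyroglobulin gene, was at 98.8% at 0h and 99.4% at 24h, Musk, a muscle receptor kinase gene, at 83.7% and 94.9%, and Ptprq at 62.7% and 89.6%. Those with the highest expression were Cyp1b1 (41.9 CPM, 69.6% at 0h and 85.9% at 24h), Smoc2, Cubn, Ly6c1 (47.6% and 100%) and Tubb3. The annotated body of H2afy2 on chromosome 10 was covered to 46.9% at 0h, 21.8% at 6h, 63.2% at 24h and 49.6% at 5d. That of H2afy was covered to 0% in all macroH2A2 libraries. The RNA counted for H2afy2 may come from the transgene, so its rise cannot be set against this coverage.

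Developmental transcription factor genes (70 genes) had a mean body coverage of 11.5% (median of matched lists 5.78%) at 0h and 17.4% (median of matched lists 14.9%) at 6h. At 24h it was 18.8% (median of matched lists 12.6%) and at 5d 16.7% (median of matched lists 10.1%). Matched lists are 10000 random lists of like expression, not matched on gene length or chromosome. High genes at 6h were at 20.1%, at 23.0% in genes of 20 kb or more and at 15.3% without chromosomes 8, 15 and 17. A list may therefore differ from its matched lists through gene length or chromosome, which was not tested. The homeobox genes Hoxd13 and Hoxc10 were covered to 100% and 99.8% at 5d and to 100% and 86.9% at 0h, Hoxc13 to 98.8% and 98.8%, and the cardiac factor gene Nkx2-5 to 96.8% and 92.2%. Tbx2, a T-box factor gene, went from 32.0% at 0h to 97.5% at 24h. Collagen and matrix genes (37 genes) were at 7.78% (median of matched lists 2.27%) at 0h, 24.9% (median of matched lists 22.7%) at 6h, 15.9% (median of matched lists 5.10%) at 24h and 13.1% (median of matched lists 3.85%) at 5d. Fibroblast markers (19 genes) were at 8.38% (median of matched lists 3.22%) at 0h, 31.2% (median of matched lists 21.1%) at 6h, 23.8% (median of matched lists 7.94%) at 24h and 22.1% (median of matched lists 5.69%) at 5d. Ribosomal genes (28 genes) were covered less at 6h than their matched lists, at 7.92% (median of matched lists 24.1%). So were integrated stress response genes at 9.76% (median of matched lists 21.5%) and cholesterol biosynthesis genes at 12.3% (median of matched lists 20.8%), the last with 0% at 0h and 24h. TGF-beta and YAP responsive genes were lower as well, at 11.3% (22.1%), as were heat shock and ER chaperones at 13.2% (22.3%) and immediate early genes at 10.6% (19.8%).

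Flavopiridol, which inhibits the transcription elongation kinase CDK9, was present for the last 18 of the 24 hours in 1 library, and mean coverage of genes of 1 CPM or more was higher there than at 24h without it. High genes were at 10.6% against 2.27%, a difference of 8.34 points, and medium genes at 23.5% against 14.1%, a difference of 9.40 points, both higher on 20 of 20 chromosomes. Relative to silent genes, high genes were covered 0.667 times as much with flavopiridol and 0.132 times without. Silent genes differed by -1.26 points, and by -1.92 in genes of 20 kb or more. Low genes differed by 1.91 points, and by -1.07 in genes of 20 kb or more. Nrp1, the neuropilin 1 gene, was covered to 3.17% at 24h, 81.8% with flavopiridol and 89.8% at 6h. It heads the 234 genes with 20% or less at 24h and 80% or more with flavopiridol, 114 of them outside chromosomes 8, 15 and 17, and the next in expression include Tuba1a, Itpr3, Reep3, Rpl36, Nfatc3, Pkd1, Ehmt2 and Rab31, of which Rab31 had the highest coverage without flavopiridol at 24h, 6.22%. Of the 1059 high genes covered at 6h and nearly uncovered at 24h, 170 (16.1%) had 50% or more covered with flavopiridol and 576 (54.4%) still had under 10%. Of 373 high genes that gained coverage in this way, 170 (45.6%) had been covered to 50% or more at 6h. Of the 24h bases 73.7% were inside the flavopiridol regions, 5.21 times independence, and 75.9% of 24h regions touched one.

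GSK126 inhibits the histone methyltransferase Ezh2 and was given for 10 days before doxycycline. At 6h, high genes were covered to 24.1% with GSK126 and 20.1% without, a difference of 4.08 points that was positive on 18 and negative on 2 chromosomes, and silent genes differed by 0.0795 points (-0.505 with regions of 2 kb or longer, 0.848 in genes of 20 kb or more), low genes by -1.34 and medium genes by -0.394. At 24h all 4 classes were covered less with GSK126. Silent genes differed by -4.05 points (-1.94 in genes of 20 kb or more) and were lower on 20 of 20 chromosomes, low genes by -7.95, medium genes by -3.91 and high genes by -0.404 points. Relative to silent genes the sign for high genes at 24h turned, at 0.142 with GSK126 and 0.132 without, and at 6h the values were 2.40 and 2.01. Upf2, Wac, Esco1 and Nktr were among the longest of 163 genes higher with GSK126 at 6h by 60 points or more, Upf2 at 75.9% against 15.2%, and Ifrd1, Cchcr1, Med20, Rer1 and Gm14325 of 113 lower genes, Ifrd1 at 0% against 65.7%. Of the 226 genes lower at 24h the longest were Adgrb2 (5.58% against 87.7%), Ttll1, Abcb9, Rasal1 and Cotl1, and of the 33 higher ones Sntb1, Ptafr, Msh5, Igfbpl1 and Lrtm1. Of the named developmental genes, Hoxc13 was covered to 98.8% at 24h and to 0% with GSK126, Tbx2 to 97.5% and 32.0%, Hoxd13 to 100% and 72.7%, Nkx2-5 to 100% and 92.2%, and Hoxc10 to 100% in both libraries. These genes were chosen for high coverage at 5d without GSK126, which leaves more room for lower values. At 6h without and with GSK126, Nkx2-5 was at 50.6% and 96.8% and Hoxc13 at 77.7% and 80.9%. Tbx2 was then at 70.7% and 16.4%, Hoxd13 at 100% and 72.7% and Hoxc10 at 100% and 99.8%. The developmental list was at 19.2% (median of matched lists 16.0%) with GSK126 at 6h against 17.4% (14.9%). At 24h it was at 12.4% (9.44%) with GSK126 against 18.8% (12.6%), so its matched lists were lower with GSK126 as well. Covered length was 392 Mb at 6h and 338 Mb at 24h with GSK126, holding 72.7% of the 6h bases (5.04 times independence, 86.5% of regions) and 72.6% of the 24h bases (5.84 times, 78.7%).

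H2A.Z, another H2A variant, was profiled in wild-type primary fibroblasts, where 45394 regions covered 203 Mb. The share of H2A.Z bases inside macroH2A2 regions, divided by the share of the genome in those regions, lay between 1.18 for 5d and 1.33 for 24h with GSK126 in the 7 libraries, with 1.28 for 0h, 1.29 for 24h and 1.22 with flavopiridol. Immediate early genes had 22.8% of the body in H2A.Z regions (median of matched lists 5.77%), developmental transcription factor genes 18.1% (7.60%) and G2/M genes 14.1% (4.19%). These cells were female and primary, so the sets also differ in cell type and sex.

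Genes with macroH2A2 over 50% or more of the body at 24h moved down in RNA at 6h. Of 517 such genes 59 rose and 130 fell, with a median log2 change of -0.17 and adjusted p = 0.00662 (8.2e-04 to 0.0534 over the alternatives). Without chromosomes 8, 15 and 17 the adjusted p was above 0.05, with 330 genes and a median of -0.16. From 6h to 24h 121 rose and 60 fell (adjusted p = 0.00602, 8.0e-04 to 0.0390 over the alternatives). This rise shares the 6h libraries with the fall, so it is not a separate result, here or in the sets below. The test compared each set with all other genes, not with genes of like expression. Only 83 high genes were covered to 50% or more at 24h and 38 at 5d. Most genes of the 24h and 5d sets thus had under 10 CPM at 0h. Of 287 genes covered at 5d 31 rose and 61 fell at 6h (adjusted p = 0.0144, 0.00362 to 0.290) and 55 rose and 30 fell from 6h to 24h (adjusted p = 0.0190, 0.00438 to 0.417), with medians of -0.17 and 0.17. Both calls were lost without chromosomes 8, 15 and 17 (171 genes, medians -0.14 and 0.094) and at 80% coverage (92 genes, medians -0.17 and 0.16). With fewer genes and medians of the same sign, the lost calls alone do not show that the change depends on these choices. Among 494 genes under 10% at 24h and at 50% or more with flavopiridol 79 rose and 169 fell at 6h (adjusted p = 0.00248, 8.0e-04 to 0.0383) and 149 rose and 68 fell from 6h to 24h (adjusted p = 0.00602, 8.0e-04 to 0.0356). The 1745 genes covered at 6h were not called at 6h (adjusted p = 0.918, median 0.0039, mean -0.013, test pointing down) or from 6h to 24h (adjusted p = 0.526), nor were the 1197 genes whose coverage was gone at 24h (adjusted p = 0.228 and 0.526). At 24h against 0h no set was called, with adjusted p of 0.580 for the sets of 6h, of lost coverage and of flavopiridol and 0.998 for those of 24h (median -0.0052, mean 0.0072, test pointing up) and 5d. Of the single genes called at 24h against 0h, 93 rose and 32 fell in the 6h set, and 74 rose and 22 fell in that of lost coverage. The latter is part of the 6h set. The counts up and down were 22 and 25 for the flavopiridol set, 12 and 6 for that of 24h and 4 and 5 for that of 5d. These counts were not tested. Across the 11122 genes with both measures, 2607 rose and 2328 fell at 6h, and 438 rose and 377 fell at 24h.

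MacroH2A2 regions covered a larger share of the bases of chromosomes 8, 15 and 17 than of the other autosomes in each of the 7 macroH2A2 libraries. The share was 21.5% against 6.10% at 0h, 29.4% against 13.3% at 6h, 27.6% against 12.7% at 24h and 27.8% against 12.1% at 5d. In the primary fibroblasts, H2A.Z regions covered 7.03% of these chromosomes and 7.91% of the others. Itgb1, Cbx5, Nrp1 and the other named genes on these chromosomes, Hoxc10 and Hoxc13 among them, are subject to this difference. Without these chromosomes, the coverage of high genes at 24h minus 6h was -13.7 points and with flavopiridol minus without 6.02 points.

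**Figure D5:**
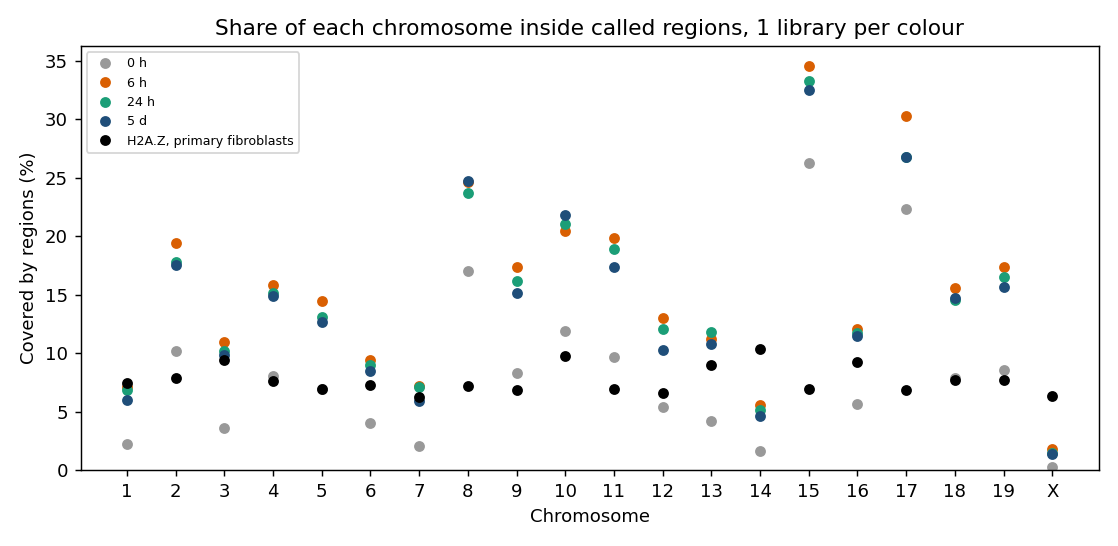
Percent of each chromosome (1 to 19 and X) covered by regions in the macroH2A2 libraries at 0h, 6h, 24h and 5d and in the H2A.Z library, 1 library each. At 24h chromosomes 8, 15 and 17 together are at 27.6% and the other autosomes at 12.7%.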

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

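All explanations were written down after the patterns themselves had been seen. The tests of deposition on these chromosomes, of the build and mapping, of doxycycline without macroH2A2 and of handling at 6h were chosen only after the result was seen. The sample groups, models, thresholds, gene lists and naming rules were fixed before the data were examined, except where a deviation is stated in the methods.

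MacroH2A2 regions covered chromosomes 8, 15 and 17 more than the other autosomes, 2.18 times as much at 24h. The genome build or mapping of these chromosomes is argued against, since H2A.Z regions from other cells on the same build covered them 0.945 times as much as the genome. Extra copies in the immortalized line may explain the pattern: the share of regions with the lowest score was higher there by a median of 34.0 points in the 7 macroH2A2 libraries (29.4 to 37.9), as weak regions passing with more reads would give, though the score's reference is not stated. More macroH2A2 deposited there cannot be told apart from this, because coverage relative to the genome differed by -0.749 for 5d minus 0h, where deposition would have raised it, but the 0h cells already held H2afy2 transcripts.

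Ribosomal protein and respiratory chain transcripts were higher at 24h, with 61 of 87 genes named Rpl or Rps with a number up and the others not called. Names of this form can include S6 kinase genes and leave out Rplp0 and Rplp1, so the count is not exact for ribosomal proteins. Better counting of short transcripts at 24h could not be excluded. Length was taken as the genomic span with introns, and transcript length was not measured, so the values cannot decide this. By genomic span, 508 other protein-coding genes under 3 kb had a median change of 0.035 (0.018 to 0.049), against 0.17 for the genes chosen by name. The 19 members of the pattern that span 10 kb or longer had 0.074. Doxycycline, which acts on mitochondrial translation, may contribute without macroH2A2, and with 0 RNA libraries outside the transgene line the design cannot tell it apart from macroH2A2. A response to macroH2A2 stays open and untested.

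Of all genes, 4980 differed between 24h and 6h in their change from 0h, tested as 24h against 6h, and most genes changed by 1.5-fold or more at 6h, which were chosen on the 6h libraries, were not called at 24h. If macroH2A2 over gene bodies at 6h lowered these genes, those that fell should have been covered more. Their mean coverage at 6h was 31.2% against 26.5% for those that rose, a difference of 4.65 points with an interval of -2.14 to 11.5 that includes 0, so this stays open. Genes not called at 6h were at 19.9%, below both groups, so those that rose were covered more as well, without a test. Handling or a medium change 6h before harvest could give such changes, and cannot be told apart with 0 libraries handled for 6h without doxycycline.

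The difference in coverage of silent genes with GSK126 was 0.0795 points at 6h and -4.05 points at 24h, opposite in sign, and this difference between times was not tested, with 1 library each. In genes of 20 kb or more it was 0.848 and -1.94 points. With regions of 2 kb or longer it was -0.505 and -4.09, of the same sign, so the opposite signs depend on the processing and the cause was not tested. For high genes it was 4.08 points at 6h and -0.404 points at 24h, also untested. Relative to silent genes of the same library, high genes were covered more with GSK126 than without at both times, at 2.40 against 2.01 at 6h and 0.142 against 0.132 at 24h, so the opposite signs depend on this choice as well.

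The 6 libraries of a contrast make 10 splits, too few for a share under 0.05. In each contrast 1 split, the real one, gave the most calls. The real split of the 6 libraries called 5538 genes for 6h against 0h and the highest other split 0, for 24h against 0h 865 and 1, and for 24h against 6h 4886 and 4. With groups of 3 libraries or 1 library, single libraries were not compared with their group.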

How the results depend on the processing

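The alternatives without chromosomes 8, 15 and 17 and with H2A.Z regions of score 3 or more were chosen only after the result was seen. Over the other tools, filters and scalings, the number of called genes was 4512 to 5538 at 6h, 762 to 1027 at 24h and 4055 to 5036 for 24h against 6h. With the replicate number as a block it was 5435, 1027 and 5036, and 5329, 951 and 4941 of the called genes remained. Leaving out 1 library gave 4667 to 5566, 553 to 1148 and 4123 to 5047. At 24h the count was 647 without 0h replicate 1, 553 without 0h replicate 2, 631 without 24h replicate 2 and 629 without 24h replicate 3, with 392, 352, 430 and 390 up and 255, 201, 201 and 239 down in that order. Without 24h replicate 1 it was 1148, with 658 up and 490 down. Fewer libraries lower the power of the test. For named genes, 1608 results under the other alternatives had the same direction and side of the threshold, and 25 lost and 2 gained a call. With 1 library left out, 2352 results were the same, 109 lost and 5 gained a call. Among the other alternatives, mt-Nd6 reversed with unstranded counts, to -0.088 at 24h against 0h and -0.15 at 24h against 6h, where counts of both strands are summed.

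With an estimated correlation 1, 0 and 1 lists were called at 6h, at 24h and for 24h against 6h, in place of 8, 9 and 10. With unstranded counts it was 8, 8 and 10, and with the replicate number as a block 8, 8 and 8. The block ended the calls of mitochondrially encoded genes at 24h (adjusted p = 0.0644) and of histone chaperones and inflammatory genes for 24h against 6h (0.0639 and 0.0763), and with the block H2afx passed for 24h against 6h (0.0327). The 5d gene set lost its RNA calls at 80% coverage (adjusted p = 0.290 at 6h and 0.417 for 24h against 6h) and without chromosomes 8, 15 and 17 (0.170 and 0.217), where the 24h set had 0.0534 at 6h, with fewer genes in each set. The ranges over all alternatives were 0.00362 to 0.290 and 0.00438 to 0.417 for the 5d set and 8.2e-04 to 0.0534 for the 24h set.

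Regions with the best scores covered 51.4 Mb at 0h, 203 at 6h, 201 at 24h, 171 at 5d, 221 with flavopiridol, 214 and 190.3 with GSK126 and 84.3 for H2A.Z, since fewer regions were counted. The wider window at 5d gave 523 Mb, 4.59 and 4.94 times independence with 24h and 0h, and 92.8% and 70.8% of regions touching. Within touched bins only, the ratios for 24h and 6h, 5d and 24h, 5d and 0h, 24h and flavopiridol, 6h and GSK126, and 24h and GSK126 were 1.68, 2.15, 2.52, 1.91, 1.85 and 2.14, since the smaller reference holds more of both. In the same order, 62.1%, 75.3%, 40.7%, 69.4%, 75.4% and 69.9% of regions were covered to 50% or more. H2A.Z ratios within touched bins were 0.458, 0.475 and 0.433 for 6h, 24h and 5d. The smaller reference lowers all of them by nearly the same factor, so their place below 1 says nothing about H2A.Z. With score 3 or more the ratios over the genome were 1.78, 1.39 and 1.01.

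Coverage of silent genes at 6h with GSK126 minus without was -0.505 points with regions of 2 kb or longer. For low genes 5d minus 6h was 3.61 points in genes of 20 kb or more and 12.6 with the wider window, and flavopiridol minus none -1.07 in genes of 20 kb or more. For high genes 24h minus 6h was -20.2 in genes of 20 kb or more and -13.7 without the 3 chromosomes, and flavopiridol minus none 9.29 and 6.02. For these changes of coverage the cause was not tested. The RPKM classes were not run. With 1 library per condition and unknown read depth, small ChIP differences cannot be resolved.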

Other observations

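The running numbers of the regions had gaps, which were looked at only after the data were seen and were not tested. At 0h 16.1% of the numbers were left out, against 3.92 to 5.52% in the other macroH2A2 libraries with the same window and 3.36% for H2A.Z. On chromosomes 8, 15 and 17, which macroH2A2 regions covered more, the share was 29.9, 29.6 and 51.5% at 0h, 13.9, 12.7 and 24.8% at 6h and 2.51, 2.41 and 4.90% for H2A.Z. At 0h it was also 28.2% on chromosome 14 and 23.2% on X, and on the other autosomes it was 9.67% or less at 0h and 4.29% or less at 6h. Macrophage and leukocyte marker genes had a mean body coverage of 46.0% at 24h (median of matched lists 21.5%), 16.6% at 0h, 25.0% with flavopiridol and 18.4% with GSK126 at 24h, over 14 genes. In the 24h library 54.4% of the covered bases lay in regions of 10 kb or wider, against 41.1% at 6h and 56.8% with flavopiridol.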
